A study of Mus musculus with 15 samples.

How the data were processed

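The data are lists of peaks from chromatin immunoprecipitation sequencing (H3K4me2, H3K27ac and ATOH1) and DNase-seq (DHS) of mouse intestinal epithelium from C57BL/6 mice. Per the labels' protocols, crypts were freed from villi by hand and with EDTA, stem cells were sorted by flow cytometry for green fluorescent protein under the Lgr5 promoter, Sec-Pro came from crypts after DBZ treatment or Rbpj deletion, goblet cells from villi without Rbpj, and Ent-Pro and enterocytes from crypts and villi without Atoh1. No sort is stated for Sec-Pro, and the share of other crypt cells in them is unknown. The labels do not say which Sec-Pro preparation served for H3K27ac, DHS and ATOH1. Of 15 samples, 12 have a peak list, and the 3 input DNA samples were not analysed here. Per the submitters' processing notes, CASAVA 1.7, Bowtie 0.12.7 and MACS2 were used with genome build mm9; no parameters are given in the sources used here, nor whether input DNA served as background. The authors deposited 1 list per library, without pooling of replicates. Per the labels, nothing says whether replicates of a group came from separate animals.

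Each deposited file has 5 columns and no header, with the chromosome, start and end of a peak (0-based), its name and the authors' score. The score is not named in the files. The lowest score lay between 2.00 and 2.72 in every list. The score was used to rank peaks within a list, to describe classes of peaks within a list and to describe the ISC list. Read numbers are not given in the sources used here, so depth is unknown, and lists differ in length for reasons that cannot be separated into depth and biology. The shortest peak differed between lists (146 bp, 200 bp, and 131 bp for ATOH1). The reason is not given in the sources used here, and the value served as a technical grouping of the libraries. The labels give the build. The ends of all peaks on assembled chromosomes were checked against the mm9 chromosome lengths in the R package GenomeInfoDb 1.38.1 and lay within them, and 34 ATOH1 peaks on unplaced contigs were kept.

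Peaks were compared in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. A peak counted as shared when at least 1 bp was overlapped. The Jaccard index is the length covered by both lists divided by the length covered by either. Progenitor-specific H3K4me2 regions were taken from the union of the 4 progenitor lists, with overlapping peaks merged, as regions with a peak in both libraries of 1 progenitor and in neither of the other. Counts were also made for the other splits of the 4 libraries. Within-group minus between-group Jaccard indices were tested by exact permutation over all 3 splits. GOB-only and ENT-only peaks are those that the other mature list does not overlap. Shares were given with Wilson 95% intervals, 2 sets of sites were compared with Fisher's exact test and paired shares with the exact McNemar test, all two-sided. Odds ratios have Wald intervals. Chance overlap was estimated by shifting peaks around their chromosomes, 100 times for ATOH1 and 20 times for pairs of lists. The intervals cover counting error only and do not include variation between animals. Sites are not replicates, so the p-values compare lists and not conditions.

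Regions were named by a rule fixed before the data were examined: the 3 highest-scoring peaks of each lineage-specific set (for H3K4me2 regions of the progenitors, by the lower of the score percentiles in the libraries) and the 3 highest-scoring ATOH1 peaks with and without a DHS in Ent-Pro, with 1-based mm9 positions. The only gene table at hand belongs to another build, GRCm38.p6, and no coordinates were converted. No gene was therefore named from a position, and the planned tests of 13 gene lists and of the E-box motif at ATOH1 peaks were not run. The same reason leaves open whether a named region lies in a gene, an exon or a promoter.

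The overlap counts were tested on simulated data drawn from 1 of the lists. With 200 and 800 peaks unique to either list, 200 and 800 were found. In 4 simulated libraries with 200 and 300 side-specific regions, 200 and 300 were found. Shared peaks had equal positions in the pair and slightly moved ends in the 4 libraries. No peaks were dropped at random, so these runs check the counting alone. Alternatives were an overlap of at least 50% of the peak, the upper 50% of each list by score, lists of equal length by score, autosomes only, merging of peaks within 1 kb, leaving out each progenitor library in turn, the share of peaks in place of the Jaccard index, and the central 200 bp of ATOH1 peaks. After the data were examined, the libraries of each shortest peak alone, the upper 50% of 1 list against the other in full, and peaks more than 1 kb from the other list were added.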

Results

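Chromatin marks, DNase I hypersensitive sites (DHS) and ATOH1 binding were mapped in epithelial cells of the mouse intestine that stood at different stages of the secretory and absorptive lineages. H3K4me2, a histone mark of promoters and enhancers, was mapped in 7 libraries. These came from Lgr5+ stem cells of the crypt (ISC, 1 library), secretory progenitors (Sec-Pro, 2 libraries), enterocyte progenitors (Ent-Pro, 2 libraries), goblet cells of the villus (GOB, 1 library) and enterocytes of the villus (ENT, 1 library). H3K27ac, a mark of active promoters and enhancers, and DHS, which marks open chromatin, were each mapped in 1 library of Sec-Pro and 1 of Ent-Pro. ATOH1, the transcription factor required for all secretory cells of the intestine, was mapped in 1 Sec-Pro library with an antibody against the FLAG tag. Sec-Pro were enriched by blocking Notch signalling, either by deletion of Rbpj (replicate 1 of H3K4me2), which encodes the DNA-binding partner of Notch, or under the Notch inhibitor dibenzazepine (DBZ, replicate 2). GOB came from villi without Rbpj, and Ent-Pro and ENT from mice with Atoh1 deleted. The labels do not say when Atoh1 was deleted. Lineage therefore cannot be told apart from genotype or treatment in comparisons of secretory with absorptive cells. The comparisons ask how far the chromatin of cells on the way to opposite fates differs, where lateral inhibition through Notch chooses between these fates.

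The H3K4me2 lists held 68407 peaks in ISC, 63293 and 92279 in Sec-Pro replicates 1 and 2, 85881 and 64138 in Ent-Pro replicates 1 and 2, 86922 in GOB and 88489 in ENT. H3K27ac gave 74483 peaks in Sec-Pro and 68764 in Ent-Pro, DHS gave 31980 and 38595, and ATOH1 gave 15240. The covered length ran from 3.41 Mb for ATOH1 to 75.0 Mb for H3K4me2 in DBZ-treated Sec-Pro. The number of reads behind each list is unknown, so a peak missing from a list is not shown to be absent from the cells. The shortest peak measured 146 bp in the lists of ISC, Sec-Pro replicate 2, Ent-Pro replicate 1, GOB and ENT. It measured 200 bp in Sec-Pro replicate 1, Ent-Pro replicate 2 and the H3K27ac and DHS lists. Each progenitor thus had 1 H3K4me2 list of either kind, and values within each kind stand beside those from both kinds below. Shares given for both libraries of a progenitor count the sites that each of them marked. Brackets after shares and odds ratios give 95% intervals, which cover counting error only. Tests over sites compare these lists and not the conditions, since sites are not replicates.

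The first comparison asked whether secretory and enterocyte progenitors differ in H3K4me2. The H3K4me2 landscapes of Sec-Pro and Ent-Pro overlapped as much as those of separate libraries of 1 lineage. Of 91486 regions in the union of the 4 progenitor lists, 42470 (46.4%) carried a peak in all 4. The Jaccard index, the shared length divided by the length covered by either list, was 0.654 between the Sec-Pro libraries and 0.688 between the Ent-Pro libraries (mean 0.671 ± 0.0239, SD, n = 2 pairs). Across lineages it was 0.742 and 0.752 for libraries with the same shortest peak (mean 0.747 ± 0.00710, SD, n = 2 pairs) and 0.684 and 0.658 for the others (mean 0.671 ± 0.0186, SD, n = 2 pairs). Shifting 1 list along the chromosomes gave mean Jaccard indices of 0.0116 and 0.0157. Similarity within lineages minus that between lineages was -0.0380, with an exact one-sided permutation p = 1 over the 3 splits of 4 libraries, of which the smallest possible is 0.333. The lists paired by shortest peak, for which the same statistic was 0.0759.

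Few regions separated the progenitors in all libraries. A peak in both Sec-Pro libraries and neither Ent-Pro library was found at 599 regions, and the opposite at 1012 regions, 1611 in all. Splitting the 4 libraries so that neither lineage nor shortest peak was shared within a side gave 832 and 788 regions, 1620 in all. The split by shortest peak gave 282 and 10081. The lineage-specific regions were short, with median lengths of 361 bp in Sec-Pro and 359 bp in Ent-Pro against 1323 bp for regions in all 4 lists. Within single pairs of libraries the counts were larger, with 16942 Sec-Pro-specific and 13628 Ent-Pro-specific regions between the 146-bp lists, and 8678 and 10507 between the 200-bp lists. Leaving out 1 library raised both counts. The Sec-Pro-specific regions numbered 15174 and 2274 without Sec-Pro replicates 1 and 2, and 4263 and 917 without Ent-Pro replicates 1 and 2. The Ent-Pro-specific regions numbered 1795, 6034, 2805 and 11050 in the same order. Most such differences lay in low-scoring peaks. Of the upper 50% by score of Sec-Pro replicate 1, 140 of 31656 peaks were absent from Ent-Pro replicate 2, and 239 of 32360 the other way round. Between the 146-bp lists, 813 of 46598 upper Sec-Pro peaks were absent from Ent-Pro and 233 of 43036 the other way round.

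**Figure D1:**
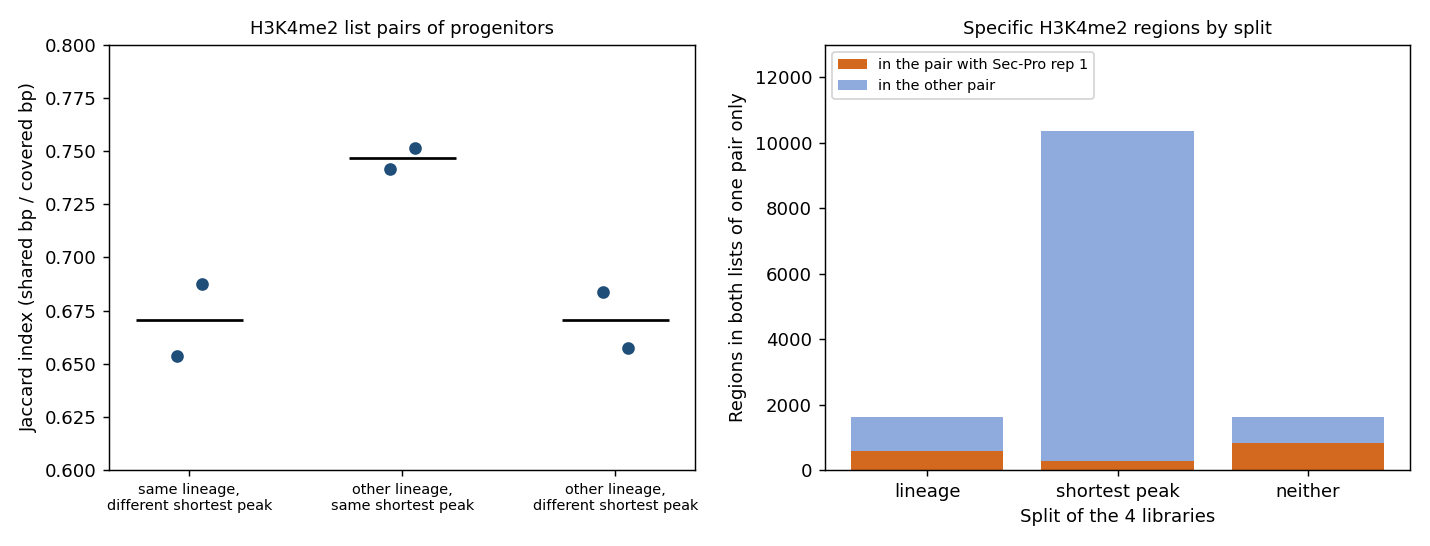
Left, Jaccard index of each pair of progenitor H3K4me2 lists (points) with the mean (line), by lineage and shortest peak, on an axis that starts at 0.6; right, number of regions found in both lists of one pair and in neither list of the other, for each split of the 4 libraries. Pairs from different lineages with the same shortest peak lay highest, at 0.742 and 0.752, and the split by lineage gave 1611 regions against 1620 for the split by neither.

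The specific regions with the strongest peaks were named by mm9 position, ranked by the lower of the score percentiles in the 2 libraries. The first Sec-Pro-specific region, on chromosome 6 at 121048203 to 121048915 (percentile 56.8), also had H3K4me2 in GOB and ENT. Its H3K27ac peak was in the Ent-Pro list. The next ones, on chromosome 10 at 88412951 to 88413366 and on chromosome 13 at 108390657 to 108391071, both had H3K4me2 in ENT. The first Ent-Pro-specific region, on chromosome 5 at 64421599 to 64422103 (percentile 63.2), had H3K4me2 in ENT and not in GOB, and H3K27ac in both progenitors. It was followed by chromosome 4 at 13519889 to 13520785, with H3K27ac in Ent-Pro alone, and chromosome 13 at 48687797 to 48688135, marked otherwise in ENT alone. Of the Sec-Pro-specific regions, 42.2% [38.3 to 46.2] were marked in GOB and 51.8% [47.8 to 55.7] in ENT. Of the Ent-Pro-specific regions, 43.8% [40.7 to 46.8] were marked in GOB and 60.4% [57.3 to 63.3] in ENT.

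A further comparison asked whether regions specific by H3K4me2 were specific by another assay too. Regions that were Sec-Pro-specific by H3K4me2 carried H3K27ac in Sec-Pro alone at 67 sites and in Ent-Pro alone at 38. For Ent-Pro-specific regions the numbers were 38 and 163. The odds ratio was 7.56 [4.44 to 12.9], with Fisher's exact p = 1e-14 (two-sided). The split of the libraries by shortest peak gave an odds ratio of 3.41 [1.92 to 6.05]. The split by neither lineage nor shortest peak gave 4.68 [2.88 to 7.61]. Between lineage and the split by neither, the difference of the log2 odds ratios was 0.69 [-0.35 to 1.73], an interval that includes 0. With single libraries the log2 odds ratio by lineage was 0.33 between the 146-bp lists and 2.11 between the 200-bp lists, against 2.92 with all 4. It was 1.04 without Sec-Pro replicate 1, 0.98 and 1.27 without Ent-Pro replicates 1 and 2, and 3.66 without Sec-Pro replicate 2. DHS present in 1 progenitor alone were too few in these regions for a like comparison, with 4 and 13 at Sec-Pro-specific and 7 and 28 at Ent-Pro-specific regions (odds ratio 1.23 [0.305 to 4.96], Fisher's exact p = 1). This DHS result passed the threshold between lists of equal length (log2 odds ratio 3.62) within each kind of list (0.77 and 1.29) and without Ent-Pro replicate 1 (1.16), against 0.30 with all 4 libraries. It was 0.81 and 1.04 without Sec-Pro replicates 1 and 2, and changed sign without Ent-Pro replicate 2 (-0.12) and with nearby peaks merged (-0.17).

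H3K27ac, compared to ask whether active regions differ between the progenitors, was shared at most sites. Of the Sec-Pro peaks, 79.8% [79.6 to 80.1] overlapped an Ent-Pro peak, and 77.4% [77.1 to 77.7] of Ent-Pro peaks overlapped a Sec-Pro peak, with a Jaccard index of 0.679. The lists left 15009 Sec-Pro-only and 15525 Ent-Pro-only peaks. This balance depended on the scaling, since lists cut to equal covered length by score left 20283 and 8023. Among the upper 50% by score, 802 of 37305 Sec-Pro peaks and 1284 of 34506 Ent-Pro peaks were absent from the other list. The highest-scoring Sec-Pro-only peak lay on chromosome 18 at 84897306 to 84897664 (score 38.3) and carried H3K4me2 in both progenitors, GOB and ENT. It was followed by chromosome 17 at 67652753 to 67653637, with DHS in both progenitors, and chromosome 17 at 74305458 to 74305909. The highest-scoring Ent-Pro-only peak lay on chromosome 4 at 116871679 to 116872972 (score 163). H3K4me2 was found there in Ent-Pro replicate 2 alone. The next ones lay on chromosome 4 at 43351992 to 43353140, with H3K4me2 in ENT and not in GOB, and at 151512376 to 151513411, with an ATOH1 peak. With 1 library on each side, no test between the conditions could be made.

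Open chromatin overlapped between the progenitors to a similar extent. Of the Sec-Pro DHS, 85.4% [85.0 to 85.7] were also found in Ent-Pro, and 70.2% [69.7 to 70.6] of the Ent-Pro DHS in Sec-Pro (Jaccard index 0.687). Strong sites open in Sec-Pro alone were rare. Only 73 of the upper 15991 Sec-Pro DHS by score lay outside the Ent-Pro list, against 1104 of the upper 19298 Ent-Pro DHS outside the Sec-Pro list. The Ent-Pro list was the longer one, and the imbalance over whole lists depended on this. In full, the lists left 4683 Sec-Pro-only and 11510 Ent-Pro-only DHS. At equal length by score they left 6562 and 6833. The highest-scoring Sec-Pro-only DHS, on chromosome 4 at 120374744 to 120375067 (score 75.7), lay under an ATOH1 peak and carried no histone mark in any list. The others named lay on chromosome 1 at 82286672 to 82287085, marked by H3K4me2 in all 7 libraries, and on chromosome 10 at 79397038 to 79397359, again under an ATOH1 peak. The Ent-Pro-only DHS with the highest scores lay on chromosome 19 at 7385208 to 7385562 (score 71.4), on chromosome 2 at 32326598 to 32326920, under an ATOH1 peak and with H3K4me2 in GOB and not in ENT, and on chromosome 17 at 28649630 to 28649995, with H3K4me2 in GOB and not in ENT. Without replicates, these numbers describe single libraries.

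Mature goblet cells and enterocytes were compared next. Of the GOB peaks, 75.2% [74.9 to 75.5] overlapped an ENT peak, and 70.8% [70.5 to 71.1] of ENT peaks overlapped a GOB peak. The Jaccard index of 0.654 equalled that of the Sec-Pro libraries (0.654), which came from different preparations and had different shortest peaks, and lay below the 0.742 and 0.752 of Sec-Pro and Ent-Pro lists of the same kind. The mature lists left 21531 GOB-only and 25823 ENT-only peaks. Among the upper 50% by score, 2438 of 43511 GOB peaks and 3407 of 44499 ENT peaks were absent from the other list, 5.60% and 7.66%. The same shares were 1.74% and 0.541% between the progenitor lists with 146-bp shortest peaks, and 0.442% and 0.739% between those with 200 bp. Libraries of 1 progenitor, which differ in shortest peak, gave higher shares in 1 direction only, for the peaks of the 146-bp list. Only that of Sec-Pro reached the mature values. Between replicates 1 and 2 the shares were 0.287% and 8.18% in Sec-Pro, and 3.93% and 0.133% in Ent-Pro.

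The highest-scoring GOB-only peak covered 5969 bp of chromosome 17, from 27860300 to 27866268 (score 136). Both Sec-Pro libraries carried H3K4me2 there, as did the Sec-Pro H3K27ac list. None of the Ent-Pro H3K4me2 and H3K27ac lists nor the ISC list had a peak in it. DHS of both progenitors and ATOH1 peaks lay within it. The next GOB-only peaks lay on chromosome 13 at 101358568 to 101358999, marked in all 4 progenitor lists, and on chromosome 7 at 28859926 to 28861091, with an ATOH1 peak and H3K4me2 in DBZ-treated Sec-Pro. The highest-scoring ENT-only peak, on chromosome 19 at 39082781 to 39083872 (score 80.7), had no peak in any other list. It was followed by chromosome 15 at 10146507 to 10147820, marked in ISC and all 4 progenitor lists, and chromosome 1 at 191841963 to 191843014, marked in Sec-Pro replicate 2 and Ent-Pro replicate 1.

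**Figure D2:**
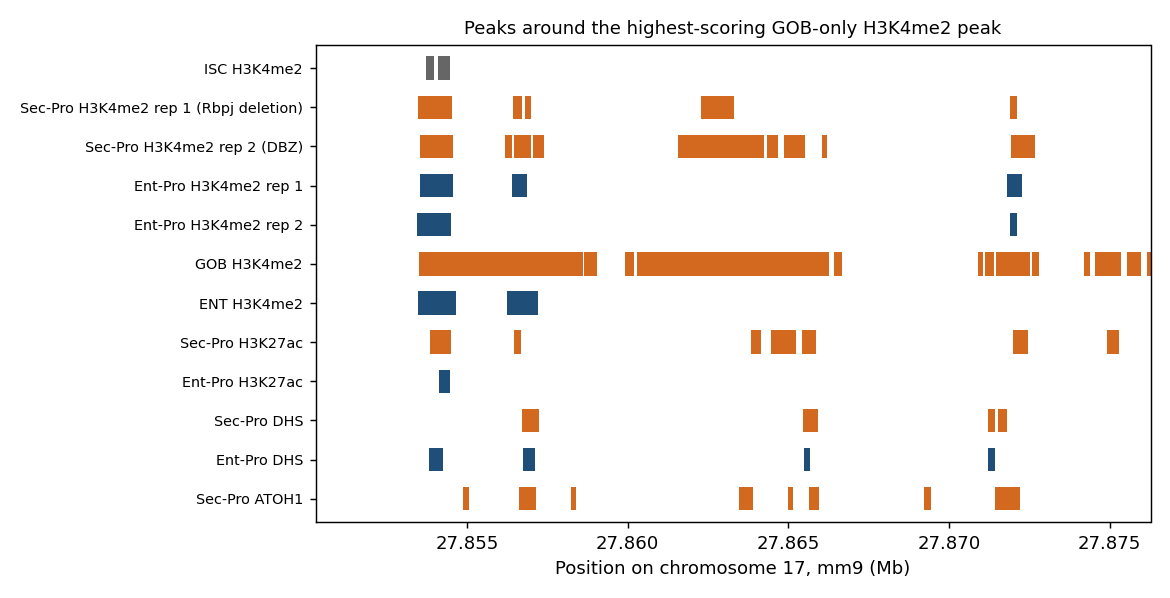
Peaks of the 12 lists (bars, to scale) along chromosome 17 of mm9, from 10 kb before to 10 kb after the highest-scoring GOB-only H3K4me2 peak; orange, Sec-Pro and GOB; blue, Ent-Pro and ENT; grey, ISC. Inside the GOB peak from 27860300 to 27866268, H3K4me2 and H3K27ac peaks are seen in Sec-Pro and none in Ent-Pro.

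Whether regions marked in 1 mature lineage were already marked in progenitors and stem cells was asked next. ENT-only peaks were marked before maturity far more often than GOB-only peaks, and in both progenitors. Both Sec-Pro libraries marked 26.995% [26.5 to 27.5] of ENT-only peaks and 8.76% [8.39 to 9.14] of GOB-only peaks, and both Ent-Pro libraries marked 30.6% [30.0 to 31.1] and 9.26% [8.88 to 9.65]. Stem cells marked 16.6% [16.1 to 17.03] of ENT-only and 7.84% [7.48 to 8.20] of GOB-only peaks (Fisher's exact p = 1.9e-185, two-sided). Sec-Pro H3K27ac covered 44.2% [43.6 to 44.8] of ENT-only and 18.7% [18.2 to 19.2] of GOB-only peaks, and Ent-Pro H3K27ac 44.1% [43.5 to 44.7] and 19.7% [19.2 to 20.2]. Open chromatin went the other way. Sec-Pro DHS lay in 6.20% [5.88 to 6.53] of GOB-only and 1.02% [0.903 to 1.15] of ENT-only peaks, and Ent-Pro DHS in 7.15% [6.81 to 7.50] and 2.02% [1.85 to 2.20].

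ENT-only peaks were marked more often in Ent-Pro than in Sec-Pro in both kinds of list, whereas for GOB-only peaks the direction depended on the kind. For GOB-only peaks, Sec-Pro exceeded Ent-Pro between the 146-bp lists, at 30.6% [30.0 to 31.2] for DBZ-treated Sec-Pro against 26.4% [25.8 to 27.02]. Between the 200-bp lists it did not, at 9.79% [9.40 to 10.2] for Rbpj-deleted Sec-Pro against 10.45% [10.05 to 10.9]. With both libraries of each progenitor required, the difference was -0.497 points (exact McNemar p = 0.00821, two-sided), and the kinds of list had no common direction. Among the GOB-only peaks in the upper 50% by score, Sec-Pro minus Ent-Pro was 9.68 points between the 146-bp lists (exact McNemar p = 3.56e-25) and 0.451 points between the 200-bp lists (exact McNemar p = 0.580). Over all GOB-only peaks, the difference without Sec-Pro replicate 1 or 2 was 21.3 or 0.534 points. Without Ent-Pro replicate 1 or 2 it was -1.69 or -17.7. For ENT-only peaks, Ent-Pro exceeded Sec-Pro between the 146-bp lists, at 46.0% [45.4 to 46.6] against 45.0% [44.4 to 45.6], and between the 200-bp lists, at 33.8% [33.3 to 34.4] against 30.8% [30.2 to 31.3]. With both libraries of each progenitor required, the difference was -3.55 points for Sec-Pro minus Ent-Pro (exact McNemar p = 2.3e-57). Requiring 1 library on one side and both on the other moves this difference by construction; without Sec-Pro replicate 1 or 2 it was 14.4 or 0.232 points, and without Ent-Pro replicate 1 or 2 it was -6.85 or -19.0. In the upper 50% by score it was -4.37 points between the 146-bp lists and -1.85 between the 200-bp lists (exact McNemar p = 6.82e-12 and 0.0118). Among ENT-only peaks more than 1 kb from any GOB peak, the 146-bp lists differed by 0.177 points (exact McNemar p = 0.614).

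**Figure D3:**
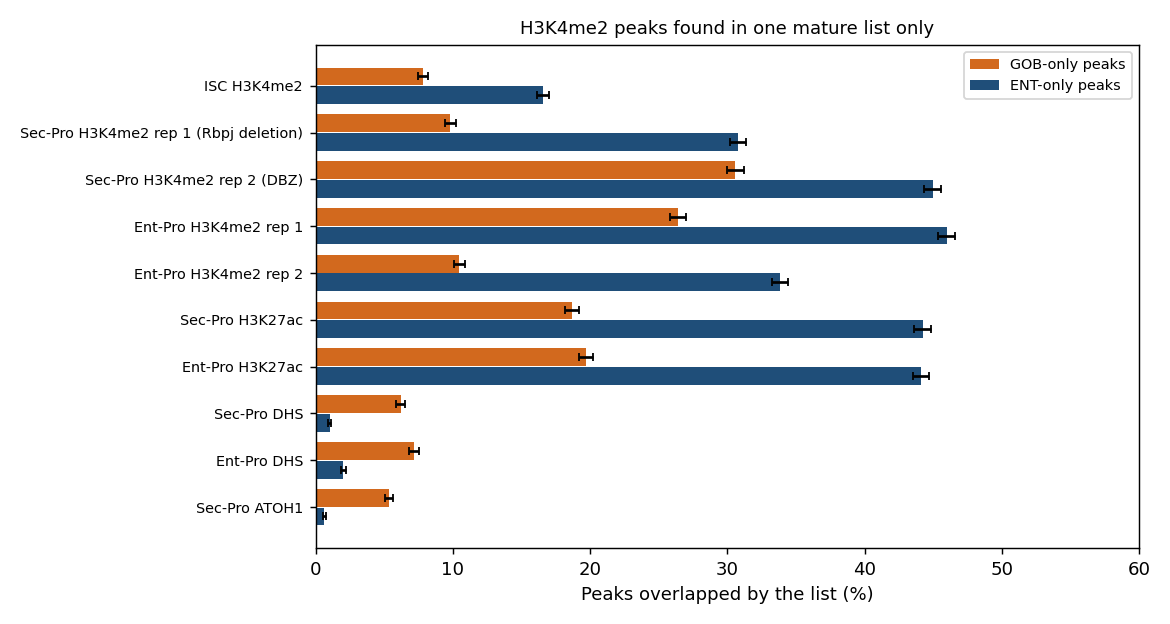
Share of H3K4me2 peaks found in GOB and not ENT (orange, 21531 peaks) or in ENT and not GOB (blue, 25823 peaks) that each other list overlaps, in percent, with Wilson 95% intervals. Histone marks of stem cells and progenitors lay more often in ENT-only peaks, whereas DHS and ATOH1 peaks lay more often in GOB-only peaks.

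Lgr5+ stem cells were compared with all other populations. Nearly all peaks of the stem cell list were found in other lists. Of 68407 ISC peaks, 49428 (72.3%) overlapped a peak in all 6 other H3K4me2 lists, and 1275 (1.86%) overlapped none. Progenitor lists held 95.9% [95.8 to 96.1] of ISC peaks in DBZ-treated Sec-Pro, 95.1% [94.9 to 95.2] in Ent-Pro replicate 1, 85.9% [85.6 to 86.1] in Rbpj-deleted Sec-Pro and 86.6% [86.3 to 86.8] in Ent-Pro replicate 2. ENT held 85.0% [84.8 to 85.3] and GOB 80.4% [80.1 to 80.7]. The mean Jaccard index with ISC was 0.448 for the 4 progenitor lists and 0.369 for the 2 mature lists. The ISC list was shorter in covered length than any other H3K4me2 list, at 33.4 Mb. Its median score (6.91) and highest score (37.7) were also the lowest among these lists. How far a weaker list raised the shares found elsewhere was not tested. The ISC values for Sec-Pro and Ent-Pro differed less than those for the kinds of list, with Jaccard indices of 0.418 and 0.420 in the 146-bp lists and 0.478 and 0.475 in the 200-bp lists. The stem cell list had no replicate.

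ATOH1 binding in Sec-Pro was set against the chromatin of both progenitors, of which Ent-Pro came from mice with Atoh1 deleted. ATOH1 sites were open and carried H3K27ac in Ent-Pro more often than in Sec-Pro. Sec-Pro DHS covered 33.9% [33.2 to 34.7] of the 15240 ATOH1 peaks and Ent-Pro DHS 37.0% [36.3 to 37.8], with 331 sites open in Sec-Pro alone and 804 in Ent-Pro alone (exact McNemar p = 6.4e-46, two-sided). H3K27ac covered 47.7% [47.0 to 48.5] in Sec-Pro and 51.4% [50.6 to 52.2] in Ent-Pro, with 365 and 920 sites in 1 progenitor alone (exact McNemar p = 1.3e-55). Of the ATOH1 sites open in Sec-Pro, 93.6% [92.9 to 94.2] were open in Ent-Pro. ATOH1 peaks shifted along their chromosomes met these lists far less often, on average at 0.920% and 1.08% for DHS and at 3.06% and 3.19% for H3K27ac. Both differences changed with list length. Equal numbers of peaks reduced that for DHS from 3.10 to 1.47 points and raised that for H3K27ac from 3.64 to 4.41 points, whereas equal covered length reduced that for H3K27ac to 1.40 points. For DHS, the ratio of Ent-Pro-only to Sec-Pro-only sites was 0.988 [0.866 to 1.13] times that of the whole lists. With lists of equal length it was 1.47 [1.30 to 1.68] times.

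H3K4me2 at ATOH1 sites was alike in the progenitors. Both Sec-Pro libraries marked 47.8% [47.0 to 48.6] of the sites and both Ent-Pro libraries 48.9% [48.1 to 49.7] (exact McNemar p = 2.7e-08). The direction depended on the kind of list, with 58.9% [58.1 to 59.7] in Sec-Pro against 58.1% [57.3 to 58.8] in Ent-Pro for the 146-bp lists, and 48.8% [48.0 to 49.6] against 49.7% [48.9 to 50.5] for the 200-bp lists. Stem cells marked 37.7% [36.9 to 38.5] of ATOH1 sites. The mature lists, 1 library each and both of the 146-bp kind, differed more in this share than progenitor lists of the same kind. They differed less than the 2 libraries of each progenitor did across kinds, at 48.8% and 58.9% in Sec-Pro and 49.7% and 58.1% in Ent-Pro. GOB marked 62.8% [62.0 to 63.5] and ENT 55.0% [54.2 to 55.8], with 1393 sites in GOB alone and 209 in ENT alone (exact McNemar p = 1.1e-214). The same contrast in peaks of the mature lists, tested after the data were examined, gave ATOH1 in 5.32% [5.03 to 5.63] of GOB-only and 0.612% [0.524 to 0.715] of ENT-only peaks, an odds ratio of 9.13 [7.72 to 10.8] (Fisher's exact p = 1.6e-232).

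**Figure D4:**
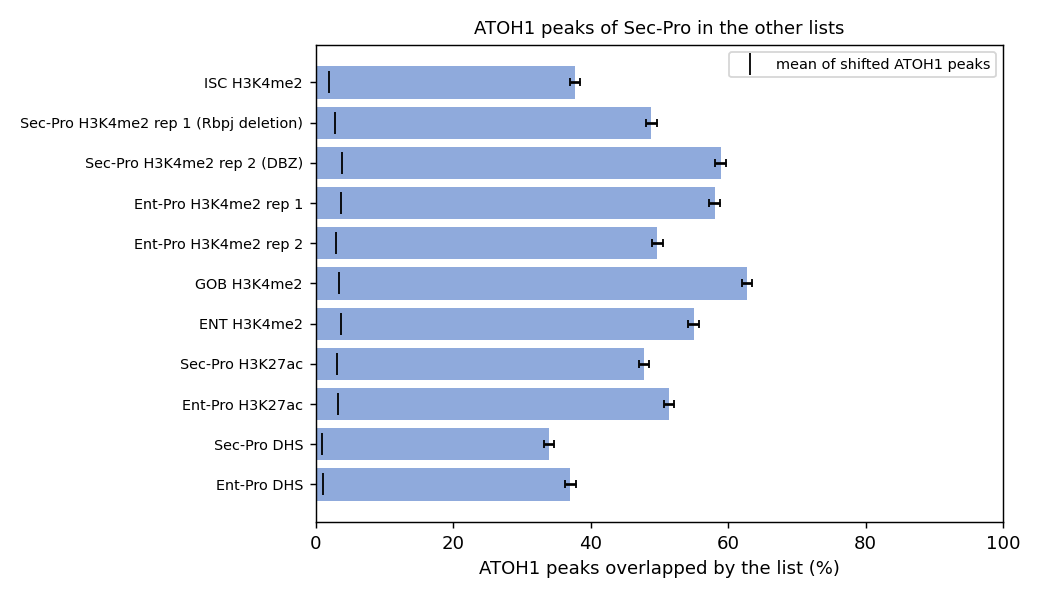
Share of the 15240 ATOH1 peaks of Sec-Pro that each other list overlaps by at least 1 bp, in percent (bars) with Wilson 95% intervals, and the mean share for 100 shifts of the ATOH1 peaks along their chromosomes (black ticks). Shares for Sec-Pro and Ent-Pro lay close together in H3K27ac, in DHS and in H3K4me2 lists of the same shortest peak, but not between H3K4me2 lists of different shortest peaks. GOB (62.8%) lay above ENT (55.0%).

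By accessibility, 4838 ATOH1 sites (31.7%) were open in both progenitors, 5118 (33.6%) were open in neither but carried a histone mark in at least 1 list, and 4149 (27.2%) had neither DHS nor mark. The last class had the lowest median score, 5.04, against 6.47 for sites open in both. The score did not rise with openness throughout. Its median was 7.59 at the sites open in neither that carried a mark. At sites open in Sec-Pro alone or Ent-Pro alone it was 8.17 and 7.75. At the 4838 shared open sites, GOB carried H3K4me2 at 93.8% and ENT at 90.8%. At the 331 sites open in Sec-Pro alone, the shares were 53.5% in GOB and 35.3% in ENT, and at the 804 sites open in Ent-Pro alone 79.5% and 71.6%. At all 9267 sites open in neither progenitor, marked or not, they were 45.5% and 35.6%. Sorted by score, the fifth of the sites with the highest scores met GOB peaks at 71.9% [70.3 to 73.5] and ENT peaks at 59.7% [58.0 to 61.5]. The fifth with the lowest scores met them at 49.0% [47.3 to 50.8] and 44.4% [42.6 to 46.2]. The highest-scoring ATOH1 peaks with an Ent-Pro DHS lay on chromosome 19 at 46592122 to 46593467 (score 309), chromosome 7 at 53014363 to 53015337 (score 297) and chromosome 7 at 19669438 to 19670326 (score 295). All 3 overlapped a peak in each of the 11 other lists. Without an Ent-Pro DHS, the first were chromosome 7 at 19592377 to 19593364 (score 250), chromosome 12 at 101542395 to 101543119 (score 208) and chromosome 1 at 177442225 to 177442797 (score 205). None of these had a Sec-Pro DHS, and the last was marked by H3K4me2 in GOB, ISC and DBZ-treated Sec-Pro but not in Ent-Pro or ENT, and by H3K27ac in Ent-Pro.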

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

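The tests of lineage as a source of similarity, of region edges, of sites with a DHS in neither progenitor and of the excess over the whole list were chosen after the results were seen, as were the comparisons in the next paragraph, the one within 146-bp lists last, and the ratios at equal length.

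Between absorptive and secretory cells, the share of ATOH1 sites with H3K4me2 differed by 1.14 points in the crypt and by -7.77 points in the villus. The difference of these differences, 8.90 points, was seen at 1769 sites against 515 in the opposite direction (exact sign test over sites, p = 4.5e-160). The crypt value counts sites marked in both lists of a progenitor, which are of different kinds, whereas both villus lists have a shortest peak of 146 bp. Between the 146-bp crypt lists the difference was -0.840 points, of the same sign as in the villus, and the difference of the differences was 6.93 points (1528 sites against 542, exact sign test over sites, p = 3.54e-108). At GOB-only peaks, Sec-Pro minus Ent-Pro gave 4.16 points with DBZ-treated Sec-Pro and -0.660 with Rbpj-deleted Sec-Pro, each against the Ent-Pro list of the same shortest peak. The difference of 4.82 points had 2835 peaks in its direction and 1809 against it (exact sign test over peaks, p = 1.5e-51), and preparation and shortest peak cannot be told apart here.

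H3K4me2 lists of progenitors resembled each other by shortest peak rather than by lineage. The values argue against the number of peaks as the whole source, but not as a part of it. With equal numbers of peaks the split by shortest peak gave 3998 regions in place of 10363. The lowest Jaccard index with the same shortest peak then exceeded the highest of a same-lineage pair by 0.0271 in place of 0.0539. Covered length, which the Jaccard index measures, was not made equal and stays open. In full it was 57.0 and 57.7 Mb in the 200-bp lists and 75.0 and 74.0 Mb in the 146-bp lists. Merging of peaks within 1 kb left a margin of 0.0586, which argues against gaps between split peaks as the source. The Jaccard index measures length, so splitting that leaves no such gaps could hardly move it. Same-lineage pairs differed by -3.4e-05 in mean Jaccard index from pairs that shared neither, and a batch of library preparation or peak calling with its own settings may underlie the pairing; this stays open because the labels give no batch.

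ATOH1 peaks lay in more GOB-only than ENT-only H3K4me2 peaks, with an odds ratio of 9.13. Among peaks with a DHS in both progenitors the odds ratio was 2.30 [1.25 to 4.23], and 12 ENT-only peaks with ATOH1 leave open how much of the pattern there follows from accessibility. Among peaks with a DHS in neither progenitor, which held 918 of the 1146 GOB-only peaks with ATOH1, it was 8.87 [7.41 to 10.6]. This argues against called DHS of progenitors as the whole source. A DHS missing from a list is not shown to be absent, so openness too weak to be called was not tested. Edges of shared regions do not account for the pattern either, since the odds ratio was 11.5 [9.23 to 14.3] for peaks more than 1 kb from the other list. Accessibility at shared DHS and openness too weak to be called stay open. A batch difference between the 2 mature lists, of which each is 1 library, stays open too. The same holds for a biological link between ATOH1 binding and H3K4me2 of goblet cells.

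Ent-Pro, from mice with Atoh1 deleted, had more ATOH1 sites in their DHS and H3K27ac lists than Sec-Pro. For H3K27ac, a greater covered length in Ent-Pro is not the whole source, as the difference stayed at 1.40 points with equal covered length (exact McNemar p = 8.9e-10). For DHS, the number of peaks is not the whole source, as the difference stayed at 1.47 points with equal numbers (exact McNemar p = 6.2e-12). These cut DHS lists still covered 15.91 Mb in Ent-Pro against 14.99 Mb in Sec-Pro. Equal covered length was not tested for DHS, so covered length stays open there. For DHS, the ratio of Ent-Pro-only to Sec-Pro-only sites was 0.988 [0.866 to 1.13] times that of the whole lists, but 1.47 [1.30 to 1.68] times with lists of equal length, and in the upper 50% by score ATOH1 lay in a larger share of Sec-Pro-only than of Ent-Pro-only DHS (odds ratio 6.62 [4.06 to 10.8]), so that a general excess of Ent-Pro-only DHS stays open as a source. For H3K27ac it was 2.44 [2.15 to 2.76] times that of the whole lists, with 920 Ent-Pro-only against 365 Sec-Pro-only sites. A general excess in the number of Ent-Pro-only peaks would not give this. At equal covered length it was 3.62 [3.21 to 4.07] times, with 708 against 495 sites. There the ratio of sites itself fell from 2.52 to 1.43, and the cut left 20283 Sec-Pro-only and 8023 Ent-Pro-only peaks. The rise to 3.62 thus came from the peak counts, and the value at equal covered length does not decide on a general excess. Quality of the single libraries and a biological difference both stay open.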

How the results depend on the processing

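The libraries of each shortest peak alone, the upper 50% of a list against the other list in full, and peaks more than 1 kb from the other list were chosen after seeing the data, as were all alternatives for ATOH1 in GOB-only and ENT-only peaks. Of 167 alternatives for 20 results, 122 left direction and side of the threshold as they were, or, without a test, moved a count by at most 1.5 times (599 to 874 Sec-Pro-specific regions with 50% overlap, for example), a share within its 95% interval or a mean Jaccard index within 1 SD. Of these, 4 could not change the value, since they leave out a library of the progenitor it does not use (ENT-only minus GOB-only shares). For the similarity of the progenitors this holds for the sign alone, since 3 splits cannot give a p under 0.333. No alternative passed these limits for the ISC comparison, ATOH1 sites with H3K27ac or DHS, ENT-only against GOB-only marks, and H3K27ac in regions specific by H3K4me2. The last also held under the split by neither lineage nor shortest peak, so this stability is not particular to lineage. The ISC difference was 0.0696 to 0.0964 in Jaccard index (main 0.0783). With shares of peaks it was 0.105, another measure set against the same limit. That limit was 1 SD of the ISC Jaccard indices with the 4 progenitor lists. Where no construction is named, the cause was not tested. Requiring 50% overlap moved the overlap of GOB and ENT from 73.0% to 66.8%, of H3K27ac from 78.6% to 72.4% and of DHS from 77.8% to 76.8%, and gave 1560 Ent-Pro-specific regions. The upper 50% of each list gave 80.7%, 84.6% and 87.3%, and 146 Sec-Pro-specific and 272 Ent-Pro-specific regions. The upper 50% against full lists gave 93.4%, 97.1% and 96.9%. Merging within 1 kb gave 80.5%, 83.0% and 78.3%, and 291 and 433 regions. Equal lengths moved DHS to 79.1%. The 146-bp libraries alone gave 16942 and 13628 specific regions and the 200-bp libraries 8678 and 10507. Leaving out 1 library gave 917 to 15174 and 1795 to 11050, since fewer lists then have to match. For Ent-Pro minus Sec-Pro at ATOH1 sites, H3K4me2 reversed with the 146-bp libraries (-0.840 points). For GOB-only peaks, Sec-Pro minus Ent-Pro (-0.497 points) no longer passed the threshold with 50% overlap (-0.300, exact McNemar p = 0.0638) or equal lengths (-0.219, p = 0.217), and reversed with the 146-bp libraries (4.16) and the upper 50% against the full list (0.533). Leaving out 1 library gave -17.7 to 21.3, reversed without Sec-Pro replicate 1 (21.3) or 2 (0.534). For ENT-only peaks it gave -19.0 to 14.4, reversed without Sec-Pro replicate 1 (14.4) or 2 (0.232). In both, 1 library on one side is set against 2 on the other by construction. The log2 odds ratio for DHS in specific regions (0.30) passed the threshold with equal lengths (3.62), the 146-bp (0.77) or the 200-bp libraries (1.29), and reversed with peaks merged (-0.17). Leaving out 1 library gave -0.12 to 1.16, reversed without Ent-Pro replicate 2 (-0.12) and past the threshold without Ent-Pro replicate 1 (1.16). No paired analysis was possible because the labels pair no samples. Links of peaks to genes within other distances and the motif alternatives were not run, for lack of mm9 annotation and genome. Without read counts, what depth limits is unknown.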

Other observations

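The comparisons in this part were chosen after the data were examined. Relative to Ent-Pro-only sites, Sec-Pro-only DHS carried H3K4me2 of GOB alone rather than of ENT alone more often, whereas Sec-Pro-only H3K27ac peaks did not. Of 4683 Sec-Pro-only DHS, 5.85% [5.21 to 6.56] carried H3K4me2 in GOB and not ENT and 1.02% [0.774 to 1.36] in ENT and not GOB. For the 11510 Ent-Pro-only DHS the shares were 4.24% [3.89 to 4.62] and 3.05% [2.75 to 3.38] (odds ratio 4.11 [2.93 to 5.75], Fisher's exact p = 1.8e-19). Sec-Pro-only H3K27ac peaks matched GOB alone at 7.18% and ENT alone at 13.3%, and Ent-Pro-only peaks at 7.12% and 11.9% (odds ratio 0.897 [0.808 to 0.997], Fisher's exact p = 0.0444). In the upper 50% by score the odds ratio was 19.2 [2.46 to 149.6] for DHS (Fisher's exact p = 0.000158) and 0.744 [0.497 to 1.11] for H3K27ac (Fisher's exact p = 0.155). ATOH1 went with Sec-Pro-only sites among high-scoring DHS and with Ent-Pro-only sites in H3K27ac. Of the 73 such DHS in the upper 50% by score, 39 (53.4% [42.1 to 64.4]) overlapped an ATOH1 peak, against 163 of 1104 (14.8% [12.8 to 16.98]) for Ent-Pro-only DHS (odds ratio 6.62 [4.06 to 10.8], Fisher's exact p = 2.2e-13). Over all such DHS without a score limit the shares were 6.15% and 6.06% (odds ratio 1.02 [0.882 to 1.17]). For H3K27ac, ATOH1 lay in 2.74% of Sec-Pro-only and 9.27% of Ent-Pro-only peaks of the upper 50% (odds ratio 0.276 [0.174 to 0.439], Fisher's exact p = 1.58e-09), and in 1.86% and 3.88% over all (odds ratio 0.469 [0.406 to 0.541], Fisher's exact p = 1.44e-26).

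GOB-only H3K4me2 peaks that held an ATOH1 peak were more often marked in stem cells and progenitors than those without. These groups were not compared at equal score or length. In the upper 50% by score, ATOH1 lay in 11.6% of GOB-only peaks, against 5.32% of all. DBZ-treated Sec-Pro marked 50.7% of these upper peaks, against 30.6% of all. How far score underlies the values below was not tested. Among the H3K4me2 lists the odds ratios were higher in the 146-bp than in the 200-bp lists, a difference that was not tested. In DBZ-treated Sec-Pro, H3K4me2 covered 52.4% [49.5 to 55.3] of the 1146 peaks with ATOH1 and 29.4% [28.7 to 30.0] of the 20385 without (Fisher's exact p = 2.2e-56). In stem cells the shares were 17.8% [15.7 to 20.1] and 7.27% [6.93 to 7.64] (Fisher's exact p = 7.7e-30). In the Ent-Pro list of the same shortest peak they were 40.5% [37.7 to 43.4] and 25.6% [25.0 to 26.2]. The odds ratios with against without ATOH1 were 2.65 [2.35 to 2.99] and 1.97 [1.75 to 2.23] in these Sec-Pro and Ent-Pro lists. In the 200-bp H3K4me2 lists the shares were 13.5% and 9.58% in Rbpj-deleted Sec-Pro (odds ratio 1.48 [1.24 to 1.76]) and 14.7% and 10.2% in Ent-Pro (1.51 [1.27 to 1.79]). The H3K27ac and DHS lists also have 200-bp shortest peaks. Their odds ratios in Sec-Pro and Ent-Pro were 1.90 and 2.02 for H3K27ac, and 3.04 and 2.53 for DHS. Between progenitors, DBZ-treated Sec-Pro marked more peaks than Ent-Pro of the same shortest peak both with ATOH1 (201 peaks in Sec-Pro alone, 64 in Ent-Pro alone, exact McNemar p = 1.2e-17) and without (1925 and 1166, exact McNemar p = 9.69e-43). Between the 200-bp lists, no difference was detected with ATOH1 (64 peaks in Sec-Pro alone, 77 in Ent-Pro alone, exact McNemar p = 0.312), and Ent-Pro marked more without it (817 and 946, exact McNemar p = 0.00229).

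DHS that overlapped no H3K4me2 or H3K27ac peak in any list, called unmarked here, made up 34.1% of the Sec-Pro and 35.6% of the Ent-Pro list. Of these unmarked DHS, 66.2% [65.3 to 67.1] in Sec-Pro and 52.4% [51.6 to 53.3] in Ent-Pro were found in the other progenitor, against 95.3% [94.98 to 95.5] and 80.0% [79.5 to 80.5] of the marked ones. ATOH1 lay in 3.16% [2.85 to 3.51] of unmarked and 21.3% [20.8 to 21.9] of marked Sec-Pro DHS. The unmarked DHS were weaker and shorter, with a median score of 10.2 against 46.5 and a median length of 255 bp against 500 bp in Sec-Pro, and 8.31 against 38.6 and 250 bp against 466 bp in Ent-Pro. Sharing and ATOH1 overlap were not compared at equal score or length. Peaks on chromosome Y numbered 26 in GOB, 28 in ENT and 6 in ISC, and 0 in the 9 other lists; the labels give no sex. Peaks on chromosome X made up 1.39% of GOB, 1.69% of ENT and 1.53% of ISC peaks, and between 1.97% and 2.08% of the peaks in the 4 progenitor H3K4me2 lists.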
